A study of Homo sapiens with 2 samples.

How the data were processed

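Total RNA of HepG2.2.15 cells was measured on 2 one-colour Agilent arrays, 1 array of untreated cells and 1 array of cells kept for 48 h in medium with 10 μmol/L entecavir. Per the labels' protocols, cells adhered for 18 h in 12-well plates in medium with 10% serum before the medium was replaced, RNA was isolated with a mirVana kit, and 0.2 μg of it was amplified and labelled with Cy3. The groups were taken from the treatment given in the labels. Each group held 1 culture and 1 array, so no p-value, no spread between replicates and no replicate check exist for any difference given here, and the number of arrays limits the precision.

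The scanner files hold spot intensity values on a linear scale, made per the file headers and the submitters' processing notes with Agilent Feature Extraction 10.7.1.1, which subtracts background to give the processed signal. Both arrays lay on 1 slide, were read in 1 scan and were extracted with 1 protocol, per the file headers, so slide and scan do not separate the groups. The authors also deposited a value table on a log2 scale, whose normalization is not given in the sources used here. Its columns had the same median, 5.81, and each correlated across probes with log2 of its own array's processed signal (Pearson r = 0.99992 for the untreated and 0.9999 for the entecavir array), which settles the scale and the direction. The equal distributions of both columns have the form that quantile normalization gives, but how the table was centred stays unknown. It was used as an alternative source of values.

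Each array held 62976 spots, of which 58717 were not controls and belonged to 50599 probes. A set of 902 probes was printed 10 times and the other 49697 were printed once. No spot was saturated on either array. The main values were log2 of the processed signal less the array's 75th percentile over non-control spots, which was 1241 intensity units on the untreated and 1196 on the entecavir array. Spots marked as non-uniform or as population outliers were left out, and the spots of a probe were averaged. A probe was taken as detected where at least 50% of its spots were well above background, and a gene was measured where a probe was detected on both arrays. A gene with several such probes was represented by the brightest. Differences are log2 values, entecavir minus untreated.

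The array's own gene names were updated through a RefSeq gene table (GRCh38.p14, used for names only). Of the probes, 28174 matched by accession, 2618 by symbol and 620 by an older symbol, and 19187 kept the name in the file. Of the 20603 genes measured, 15498 had a name in that table. Probe coordinates are those of the array files, on hg19 per the file headers.

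The technical error of a difference was the SD that repeated spots of the probes printed 10 times imply for a difference of single spots, in 4 equal groups of genes by signal. It was 0.31 in the dimmest group, then 0.10, 0.06 and 0.05 in the brightest. For a probe printed 10 times it was reduced accordingly. It covers spot noise and leaves out differences between cultures, RNA preparations and labelling reactions. The E1A and ERCC spike-in probes gave signals near background on both arrays (median intensity 8.92 and 6.17 for E1A), so they gave no measure of scaling.

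Before the data were examined, 38 gene lists were fixed. For each, the median difference of the measured members was set against 10000 random lists of the same size matched on mean signal in 20 bins, and a list was said to stand apart where its median lay outside their central 95%. The percentile describes these 2 arrays and is not a test between conditions. With 38 lists, 1.9 would stand apart by chance if the members of a list varied independently. Members of real lists can vary together and some lists share genes, so the number reached without an effect may be higher. The rule for named genes, also fixed before the data were examined, took the 12 highest and 12 lowest differences among genes with a symbol that were brighter than the median gene or had at least 2 detected probes differing in the same direction, the 4 largest bounds on each side among genes detected on 1 array only, the 2 highest and 2 lowest members of each list, and a set of nucleoside kinase, transporter, mitochondrial and hepatocyte genes. For a gene detected on 1 array only, the bound is its signal there less the higher of its own signal on the other array and the lowest signal of a detected probe on that array.

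The calculation was tested on simulated arrays with the signals of the untreated array and normal spot noise of a set size (20603 genes). The genes set apart were drawn only from those brighter than the median gene. Of genes set 2.5-fold or 4-fold apart, 100% (68 and 63 genes) were counted as at least 2-fold apart, of 68 genes set 1.5-fold apart 0% were, and a list shifted by 0.3 lay at percentile 100. These shares therefore do not show how well differences of dim genes are recovered. Of 20372 unchanged genes 0.0245% were counted. Normal noise lacks the outlying spots of these arrays, so that share is no estimate of false calls here. Repeatedly printed probes gave real spot pairs, each of an untreated and an entecavir spot. The probe's mean difference was subtracted from the difference of each pair. Of the resulting values, 3.49% in the dimmest of the 4 signal groups and 0.446% in the next were at least 2-fold in size. The alternatives were normexp background correction (offset 50), median scaling, quantile normalization, cyclic loess, no filter and a stricter filter on dim probes, keeping the marked spots, the mean of all probes of a gene, the authors' table, thresholds of 1.5-fold and 3-fold, and random lists not matched on signal. Alternatives chosen after seeing the data were matching on probe GC content as well as signal, removing the trend with GC content, and counting only genes supported by several probes or spots. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. Viral transcripts were not analysed here, and some genes that the rule for named genes takes are not reported here.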

Results

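HepG2.2.15 is a human hepatoblastoma line derived from HepG2 that carries integrated hepatitis B virus genomes and releases virus. Entecavir is a guanosine nucleoside analogue that, once phosphorylated in the cell, blocks the viral polymerase. The comparison asked which cellular transcripts differ after 48 h in 10 μmol/L entecavir. It rests on 1 untreated and 1 entecavir array, so "higher" and "lower" describe these 2 arrays, and no difference could be set against a spread between cultures. The value after ± is the technical SD of a log2 difference, which covers spot noise only. The untreated array had 59.7% of its non-control spots well above background and the entecavir array 60.8%. On both arrays 20603 genes were measured, and their signals correlated across genes with Pearson r = 0.994 (genes are not independent replicates). The median difference of all measured genes was -0.05, so a list median near -0.05 marks no shift from the other genes. The SD across single genes was 0.33. Differences also fell with the GC content of the probe (Spearman r = -0.21 across detected probes). Their median was 0.02 for probes with at most 35% GC and -0.13 for probes with at least 55%. Values of single genes with GC-rich probes can therefore hold a part of this trend.

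Replication-dependent histone genes, which encode the core and linker histones made for new chromatin in S phase, were lower on the entecavir array. All 30 measured members were lower, 12 of them by at least 1.5-fold, with a median log2 difference of -0.55 (interquartile range -0.67 to -0.45), or 1.47-fold. H3C15 differed by -1.23 ± 0.05 and H2AC6 by -0.98 ± 0.06, and the other 2 detected probes of H2AC6 differed by -0.19 and -1.06. The members nearest to no difference were H3C1 at -0.09 ± 0.05 and H2BC12 at -0.23 ± 0.05. The medians by class were -0.54 for H1, -0.71 for H2A, -0.49 for H2B, -0.58 for H3 and -0.45 for H4. The list median lay below all 10000 matched random lists (central 95% from -0.12 to 0.02). The copies of a histone gene are close in sequence, so the values of single members are uncertain; the H3C15 probe lies at chromosome 1, 149824626 to 149824685 (hg19).

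Targets of p53, the transcription factor activated by DNA damage and other stress, were higher on the entecavir array. Of 30 measured members 25 were higher, with a median of 0.23 (interquartile range 0.15 to 0.37), or 1.18-fold, above all matched random lists (central 95% from -0.12 to 0.02). MDM2, the ubiquitin ligase that limits p53, differed by 0.72 ± 0.05, and its probe lies at chromosome 12, 69238891 to 69238950. All 4 detected MDM2 probes were higher, but others gave only 0.08 and 0.32, so the size of the difference is uncertain. The cell cycle inhibitor CDKN1A differed by 0.39 ± 0.06 and the secreted stress factor GDF15 by 0.40 ± 0.05. RRM2B, the p53-induced subunit of ribonucleotide reductase, differed by 0.53 ± 0.10 at 1 probe and by -0.09 at the other. The lowest members were SESN2 at -0.15 ± 0.06 and GADD45A at -0.06 ± 0.05. By the brightest probe of each gene, MDM2 was the only member at least 1.5-fold apart.

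**Figure D1:**
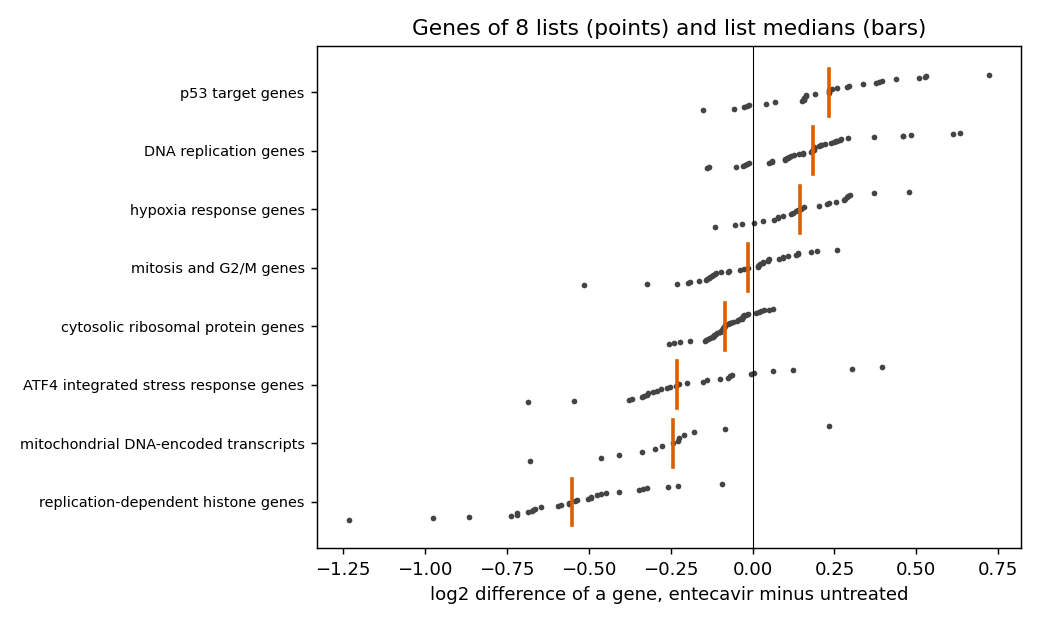
Log2 difference of each measured gene (points, horizontal axis, entecavir minus untreated, 1 array per group) in 8 gene lists, with list medians as bars. All 30 histone genes lie below 0, whereas 25 of 30 p53 targets and 37 of 44 DNA replication genes lie above it.

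DNA replication genes were also higher, in contrast to the histone genes that are made in the same phase of the cell cycle. Of 44 measured members 37 were higher, with a median of 0.18 (interquartile range 0.10 to 0.25), above all matched random lists (central 95% from -0.11 to 0.00104). MCM10, which helps to start replication forks, differed by 0.63 ± 0.10, and CCNE2, a cyclin of the entry into S phase, by 0.61 ± 0.06. The replicative helicase subunits MCM5 and MCM6 had the lowest values, -0.14 ± 0.05 and -0.13 ± 0.05. DNA damage response and repair genes had a median of 0.08 at percentile 99.97, with 22 of 38 members higher. That median ranged from 0.050 with the GC trend removed to 0.13 in the authors' table. Among them FANCD2, of the crosslink repair pathway, differed by 0.64 ± 0.06 and the recombination gene BRCA1 by 0.58 ± 0.02, against -0.70 ± 0.06 for XPA and -0.57 ± 0.06 for APEX1. The XPA value was not shared by its other probe in direction, and the other probes of FANCD2 gave 0.23 and 0.51. Mitosis and G2/M genes lay within the range of matched lists (median -0.01, percentile 93.1), with CDC25A at 0.26 ± 0.06 and PLK1 at -0.51 ± 0.06.

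Transcripts encoded by mitochondrial DNA were lower on the entecavir array. Of 13 measured, 12 were lower, with a median of -0.24 (interquartile range -0.34 to -0.21) at percentile 0.05 of matched lists. The median was -0.12 under cyclic loess and still below its range. ATP8, a subunit of ATP synthase, differed by -0.68 ± 0.05 and ND1, a subunit of complex I, by -0.46 ± 0.05. ND6 was the exception at 0.23 ± 0.10. COX1 differed by -0.08 ± 0.05, but its probe is placed in the array file on chromosome 1, where a nuclear copy lies, so that value is uncertain, and it changed sign under quantile normalization, loess and the authors' table. Nuclear-encoded oxidative phosphorylation genes had a median of -0.12 within the matched range (percentile 7.09), with 40 of 43 lower. Genes that maintain mitochondrial DNA had a median of -0.09 (percentile 16.6), with 21 of 30 lower. The DNA polymerase gene POLG stood at 0.04 ± 0.05 and TFAM, which packages mitochondrial DNA, at -0.04 ± 0.05. The lowest member was LIG3 at -0.46 ± 0.10 and the highest RRM2B at 0.53 ± 0.10 by its brighter probe.

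Genes of the ATF4 integrated stress response, which are induced by amino acid shortage, were lower. Of 28 measured members 23 were lower, with a median of -0.23 (interquartile range -0.32 to -0.07), below all matched random lists (central 95% from -0.13 to 0.01). In the authors' table the median was -0.14. CHAC1, a glutathione-degrading enzyme, differed by -0.69 ± 0.10 and asparagine synthetase ASNS by -0.55 ± 0.05. GDF15, which the p53 list also holds, and VLDLR at 0.30 ± 0.06 were the highest members. The unfolded protein response list lay within the matched range (median -0.10, percentile 14.4). So did the NRF2 and oxidative stress list (median -0.08, percentile 32.4), with GCLM at 0.48 ± 0.05 and HMOX1 at -0.48 ± 0.02.

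Hypoxia response genes were higher in 23 of 26 cases, with a median of 0.14 (interquartile range 0.08 to 0.27), above all matched random lists, and of 0.22 under quantile normalization and 0.23 in the authors' table. The mitophagy receptor BNIP3L differed by 0.48 ± 0.05 with all 3 detected probes higher, though the others gave only 0.16 and 0.09. The glucose transporter SLC2A3 differed by 0.37 ± 0.06 at its brighter probe and in the other direction at the second. SLC2A1 and VEGFA stood at -0.11 ± 0.05 and -0.05 ± 0.05, and their other probes gave -0.63 and 0.05. The glycolysis list lay within the matched range (median -0.03, percentile 88.1).

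Secreted liver proteins of the acute phase, complement and coagulation list were lower in 28 of 36 cases, with a median of -0.14 (interquartile range -0.32 to -0.04) at percentile 0.72. Haptoglobin, HP, which binds free haemoglobin, differed by -0.97 ± 0.05, and fibrinogen alpha, FGA, by -0.68 ± 0.05 with all 3 detected probes lower. SAA4 and F5 were the highest at 0.31 ± 0.02 and 0.23 ± 0.06. Hepatocyte secretory and differentiation genes lay within the matched range (median -0.09, percentile 20.6). Albumin, ALB, stood at 0.07 ± 0.05 and alpha-fetoprotein, AFP, at -0.02 ± 0.05, both among the brightest genes. The transcription factor HNF4A stood at -0.39 ± 0.31 from a dim probe. Fetal liver and hepatoma genes had a median of -0.04 (percentile 77.96).

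Genes that handle nucleosides and deoxynucleotides, the pathway that activates entecavir, lay within the matched range as a list of 53 (median -0.02, percentile 96.8). This reading depended on the setting, since the list stood above its range under quantile normalization (0.056), loess (0.067), the authors' table (0.067) and with the GC trend removed (-0.017). Ribonucleotide reductase subunit RRM2 differed by 0.75 ± 0.06, although 1 of its 3 detected probes differed the other way. Deoxycytidine kinase, DCK, stood at 0.32 ± 0.06 and cytosolic thymidine kinase, TK1, at 0.24 ± 0.05. The mitochondrial kinases DGUOK and TK2 stood at -0.11 ± 0.05 and -0.07 ± 0.10. The nucleoside transporters SLC29A1 and SLC29A2 stood at 0.14 ± 0.05 and -0.15 ± 0.31. SLC10A1, the bile acid transporter through which hepatitis B virus enters, was well above background on the entecavir array only, and its signal there was too low to give a fold. Hepatitis B virus host factor genes had a median of -0.09 (percentile 17.5), and APOBEC3G, a cytidine deaminase, differed by 1.33 ± 0.31 at a single dim spot.

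Interferon-stimulated genes had a median of 0.06 (interquartile range -0.06 to 0.14) at percentile 99.4, with 25 of 38 higher and none by as much as 1.5-fold. With the GC trend removed the median was 0.039. PARP14 differed by 0.51 ± 0.06 and XAF1 by 0.50 ± 0.10, against -0.55 ± 0.31 for IFIT2. The other probe of XAF1 gave 0.00018. Cytochrome P450 and drug-metabolism genes had a median of 0.08 at percentile 99.6, with 16 of 28 higher. CYP1A1, which the aryl hydrocarbon receptor induces, differed by 0.77 ± 0.10 and POR, the reductase of these enzymes, by -0.50 ± 0.05. The other probe of POR gave only -0.17. The median of this list was -0.0094 under the stricter filter on dim probes and 0.021 with the mean of probes, where it no longer stood apart, and 0.046 with the GC trend removed, where it did. Apoptosis genes (median 0.03, percentile 98.7, 21 of 39 higher) and extracellular matrix genes (median 0.04, percentile 97.53, 24 of 35 higher) stood apart by little, and both lost this under other settings. Their medians ranged from -0.0082 to 0.080 and from 0.015 to 0.076 over the settings. BAX, a p53-induced death effector, differed by 0.38 ± 0.02 and the smooth muscle gene TAGLN by -0.87 ± 0.10. Their other probes gave 0.19 and -0.61.

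The remaining lists lay within the range of matched lists. Their medians were -0.03 for antigen presentation, 0.01 for NF-kB and inflammatory genes, -0.02 for drug and bile acid transporters, -0.11 for cholesterol biosynthesis, -0.06 for fatty acid synthesis and lipid storage, and -0.07 for fatty acid oxidation and PPARA targets. They were -0.02 for metallothioneins, -0.05 for heat shock genes, 0.04 for immediate early genes, -0.09 for cytosolic ribosomal proteins, -0.08 for proteasome genes and -0.04 for WNT targets. Cholesterol biosynthesis stood below its range under quantile normalization (-0.10), loess (-0.094), the authors' table (-0.095) and with the GC trend removed (-0.17). Single members stood out within some of them: the chemokine CXCL1 differed by -3.49 ± 0.31 at 1 dim spot, the fatty acid carrier FABP1 by -0.62 ± 0.05, and PCK1 of gluconeogenesis, in the hepatocyte list, by 0.65 ± 0.10. Altogether 13 of the 38 lists stood apart, 9 above and 4 below.

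**Figure D2:**
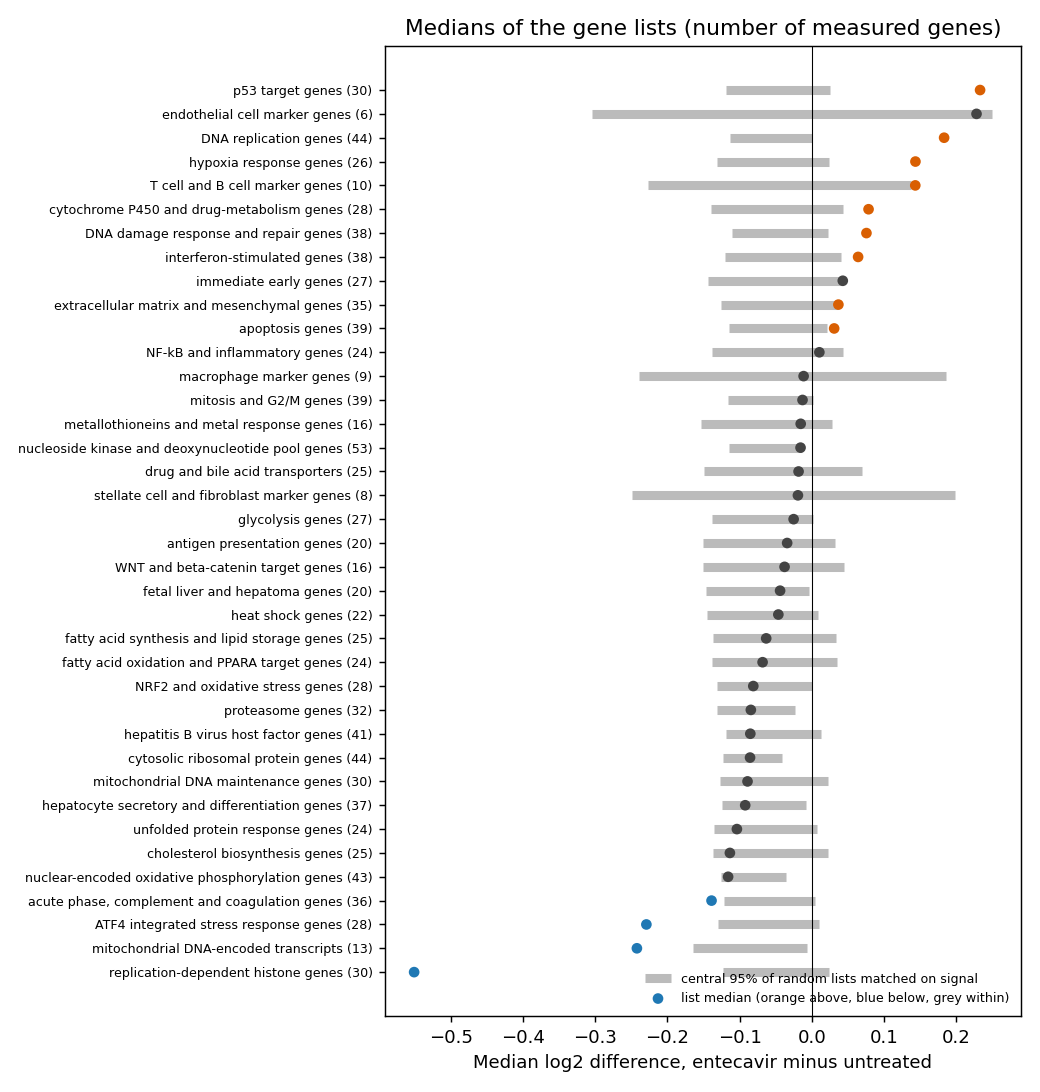
Median log2 difference (horizontal axis, entecavir minus untreated) of the 38 gene lists, with the number of measured genes in brackets and grey bars for the central 95% of 10000 random lists matched on signal. Orange points (9) lie above and blue points (4) below their bar, and the histone list at -0.55 lies farthest from its bar.

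Markers of other cell types had median signals at percentile 44.4 of all measured genes for macrophages, 24.1 for T and B cells, 22.5 for endothelial cells and 30.2 for stellate cells and fibroblasts. Macrophage markers were detected in 10 of 12 cases on the untreated and 9 on the entecavir array, T and B cell markers in 10 on both, endothelial markers in 6 and 7, and stellate cell and fibroblast markers in 8 on both. Their list medians were -0.01, 0.14, 0.23 and -0.02. The T and B cell list, with 10 measured genes, stood barely apart (percentile 97.8, central 95% up to 0.138). It no longer did so under normexp (0.091), quantile normalization (0.14), loess (0.16), no filter (0.11), marked spots kept (0.14), the mean of probes (0.035) and the authors' table (0.15). CD3D was its highest member at 0.65 ± 0.06 against -0.78 ± 0.31 for CD2. The endothelial list held 6 measured genes and lay at percentile 96.6.

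At least 2-fold differences were found for 283 of the 20603 genes, 135 higher and 148 lower. Only 10 of them, 2 higher and 8 lower, were brighter than the median gene. The ranking that follows covers genes with a symbol that were brighter than the median or had at least 2 detected probes differing the same way. The highest values there belonged to EFCAB10 (1.43 ± 0.31), NDRG4 (1.199 ± 0.06) and FAM151A (1.19 ± 0.10). Next came ADAMTS4 (0.99 ± 0.06), a protease of cartilage proteoglycan, TEX19 (0.99 ± 0.06), FBXO6 (0.98 ± 0.06), NECTIN4 (0.95 ± 0.06), CYSRT1 (0.94 ± 0.06), UBE2V2 (0.87 ± 0.06), FXYD3 (0.80 ± 0.06), ILDR1 (0.79 ± 0.02) and SLC4A11 (0.79 ± 0.05). The other probe of CYSRT1 gave 0.90 and that of FXYD3 0.68, whereas those of FAM151A and EFCAB10 gave 0.32 and 0.01. ILDR1, a receptor of tricellular junctions, was measured by a probe printed 10 times.

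In the same ranking of genes with a symbol, the lowest values belonged to ZNF773 (-3.61 ± 0.10) and GRAP (-2.39 ± 0.31), but their other probes gave -0.28 and -0.03. They were followed by MYBPH (-1.32 ± 0.06), H3C15, SCARNA13 (-1.05 ± 0.06), SNORA73A (-1.05 ± 0.06), ZNF875 (-1.04 ± 0.06), H2AC6, HP, SNORA27 (-0.94 ± 0.06) and SNORA73B (-0.93 ± 0.06). SCARNA13 and the SNORA genes encode small RNAs of the Cajal body and the nucleolus, and the other probe of SNORA73B gave -0.81. The other probe of ZNF875 differed the other way, by 0.29.

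**Figure D3:**
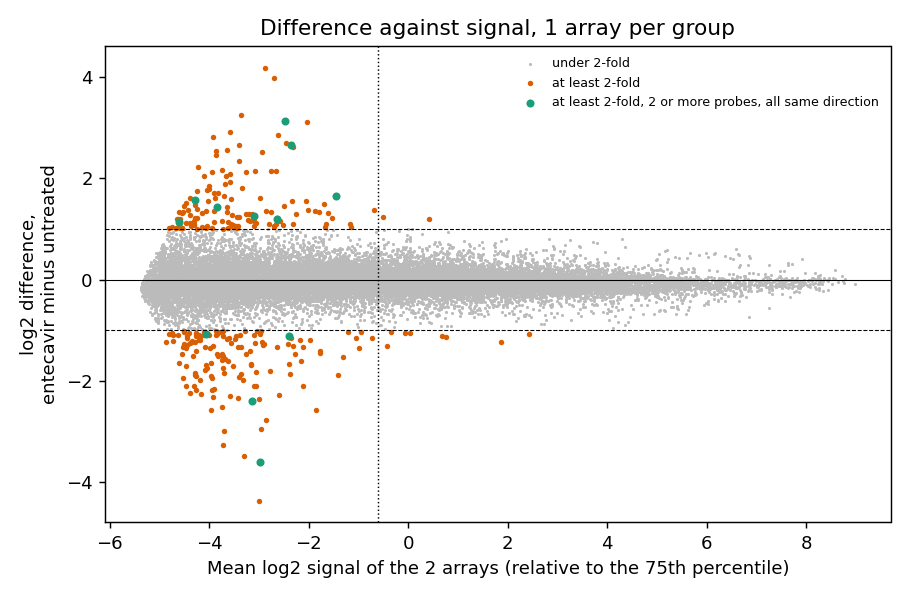
Log2 difference (vertical axis, entecavir minus untreated) against the mean log2 signal of both arrays (horizontal axis, relative to the 75th percentile) for 20603 genes, with dashed lines at 2-fold and a dotted line at the median signal. Of the 283 genes at least 2-fold apart (orange, or green where 2 or more probes differed the same way), 273 lie left of the dotted line.

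A second detected probe existed for 33 of the genes at least 2-fold apart, and it differed in the same direction in 13 of them (39.4%, exact 95% interval 22.9 to 57.9%). Among all 5018 genes with such a probe the share was 65.0%. Of 687 detected probes printed 10 times, only EBI3, a cytokine subunit, was at least 2-fold apart, at 1.09. A further 1203 genes were detected on the entecavir array only and 848 on the untreated array only. The largest bounds were for SERTAD4BP (at least 18.1-fold higher), GOLGA6L5P (13.2), CACHD1 (12.4) and DNAH5 (9.0) on the entecavir array, and for ZNF610 (29.5), PRAMEF14 (25.8), PHF24 (19.3) and RTP1 (13) on the untreated array. Each of these rested on a single spot. SERTAD4BP had 3 probes, and GOLGA6L5P, DNAH5 and PRAMEF14 had 2 each. Only 1 probe of each of these 4 genes was detected, so their other probes did not share the difference.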

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

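Spike-in control probes, which no comparison used, were more often well above background on the entecavir than on the untreated array. For the E1A controls the share of spots was 14.3% on the entecavir and 9.43% on the untreated array (50 and 33 of 350 spots). For the ERCC controls it was 11.8% and 10.65% (398 and 358 of 3360 spots), with 4 and 3 of the 96 probes above background at all of their spots. The negative control probe was above background at 9 and 7 of 308 spots. The median intensities went the other way, at 6.17 on the entecavir and 8.92 on the untreated array for E1A and at 5.74 and 6.75 for ERCC. No explanation of these values was tested.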

How the results depend on the processing

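The probe support, GC matching and GC trend settings were chosen after seeing the data. Of 13 lists standing apart, 9 did so in the same direction under all alternatives that gave a value: histone (-0.56 to -0.50), mitochondrial DNA (-0.26 to -0.12), ATF4 (-0.24 to -0.14), acute phase (-0.19 to -0.11), p53 (0.23 to 0.28), DNA replication (0.17 to 0.22), hypoxia (0.14 to 0.23), DNA damage (0.05 to 0.13) and interferon (0.04 to 0.09). Scaling moved the median of all genes by at most 0.04. The causes of the changes below were not tested, except that thresholds, filters and probe support count other sets by construction. The 2-fold count of 283 was 1244 at 1.5-fold, 96 at 3-fold, 99 with normexp, 3014 with no filter, 15 with the stricter filter and 13 with probe support; the share higher was 47.7%, against 20% with the stricter filter and 69.2% with probe support. Dim signal limits it: no gene brighter than the median was 3-fold apart.

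Lists that no longer stood apart were apoptosis with unmatched lists (0.031) and loess (0.060); extracellular matrix with unmatched lists and with GC matching (both 0.037), loess (0.067), no filter (0.031), the stricter filter (0.015), the authors' table (0.076) and GC trend removed (0.021); T and B cell markers with normexp (0.091), quantile (0.14), loess (0.16), no filter (0.11), marked spots kept (0.14), mean of probes (0.035) and the authors' table (0.15); and P450 with mean of probes (0.021). With the stricter filter P450 (-0.0094) and apoptosis (-0.0082) changed sign. Lists that newly stood apart were immediate early with GC matching (0.043); endothelial with unmatched lists (0.23), normexp (0.22), no filter (0.25) and GC trend removed (0.27); cholesterol with quantile (-0.10), loess (-0.094), the authors' table (-0.095) and GC trend removed (-0.17); nucleoside with quantile (0.056), loess (0.067), the authors' table (0.067) and GC trend removed (-0.017); glycolysis with the stricter filter (-0.0027) and GC trend removed (0.020); and nuclear oxidative phosphorylation with GC trend removed (-0.14). With the mean of probes CD44 (-0.0024) and SAMHD1 (0.050) changed sign, 41 of 182 named genes moved by more than their technical SD and 139 did not. So did 34 under normexp, 8 under median scaling, 55 under quantile and under loess, 58 in the authors' table and 52 with GC trend removed. COX1, GADD45A, TFAM, AFP, SDHA and IDI1, all within 2 technical SD of 0, changed sign under some of these settings. Lists with under 5 members left by the stricter filter gave no value. E1A centring was not run, as those probes lay near background, nor was leaving out saturated spots, as there were none. No paired analysis was possible because the groups share a single replicate number.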

Other observations

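The gene families and histone variants in this part, and the tests of second probes, of spot noise by signal group, of S phase and of short transcripts, were chosen only after the results were seen, as were the random lists matched on GC content. Small RNA and mitochondrial ribosome genes were lower together on the entecavir array. SNORA genes, most of which encode guides for pseudouridylation, had a median of -0.28 over 99 measured genes, 23 of them lower by at least 1.5-fold, and SNORD genes, most of which encode guides for methylation, had a median of -0.15 over 122. Proteins of the mitochondrial ribosome were lower too: the MRPL genes had a median of -0.17 with 7 of 52 higher, and the MRPS genes -0.16 with 7 of 29 higher. Zinc finger genes of the ZNF family had a median of 0.06 over 447 genes, with 278 higher, and GOLGA genes 0.14 over 21. These 6 families were among 14 of 69 that lay outside the central 95% of random lists matched on signal and, separately, on signal and GC content. Each kept its sign under all 6 scalings, with ranges of -0.28 to -0.21 for SNORA, -0.17 to -0.08 for MRPL and 0.05 to 0.08 for ZNF.

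Most histone genes outside the fixed list were also lower, with medians of -0.49 for H1 (3 of 4 genes lower), -0.61 for H2A (9 of 9), -0.47 for H2B (10 of 10), -0.43 for H3 (5 of 6) and -0.55 for H4 (6 of 6). Of the variants made outside S phase, the linker histone H1-10 differed by -0.57 ± 0.06. H2AX stood at 0.08 ± 0.05, H2AJ at 0.11 ± 0.05, and H2AZ1 and H3-3A at -0.01 ± 0.05 and -0.09 ± 0.05, the last 2 changing sign between scalings. The 12 mitochondrial genes placed on that chromosome had a median of -0.26, whereas the medians of chromosomes 1 to 22 and X lay between -0.07 and -0.02.

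The genes at least 2-fold apart were mostly dim, and noise of single spots may account for many of them. Second probes differed in the same direction in 39.4% of 33 such genes (exact 95% interval 22.9 to 57.9%), which includes the 50% of chance. From the probes printed 10 times, spot noise alone would put 206 single-spot genes (121 to 339) at least 2-fold apart, against 282 observed. In the dimmest of the 4 signal groups it would give 178 (112 to 266) against 188 observed, but in the next group 22.5 (8.25 to 48.8) against 84, above that range. The ranges treat spot pairs as independent, although each probe gave several, and the next group's rests on 6 of 1346 pairs. The range for 206 adds the limits of the 4 groups, so all of them are approximate. Whether anything besides spot noise set the genes of that next group apart stays open, and 1 array per group cannot show whether the cultures differed.

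The lower histone genes were not accounted for by GC content, but weaker labelling of their RNA and a loss of short transcripts stay open. Against random lists matched on GC content as well as signal, the median differed by -0.46 from theirs. Small nuclear and nucleolar RNAs, which also lack a poly(A) tail, had a median of -0.20 over 259 genes (bootstrap 95% interval -0.24 to -0.14), and SNORA genes alone -0.28. Weaker labelling of RNA without such a tail could therefore explain a part. Whether it explains the whole stays open, since it was only assumed to act equally on both kinds of RNA. A loss of short transcripts would lower ribosomal protein mRNAs, whose median was -0.085 (-0.097 to -0.046), within the range of matched lists. That value was known when the test was chosen. The small RNAs given above are also short and were lower, so the ribosomal protein genes cannot decide this question. Fewer cells in S phase is a biological candidate explanation. The DNA replication genes had a median of 0.18 and were higher, but this was known when the test was chosen. Their transcripts also do not measure DNA synthesis or the share of cells in S phase, so the explanation stays open. An effect of entecavir and a difference between the cultures unrelated to it both stay open, since each group held 1 culture.

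The higher medians of p53 target and DNA replication genes were weighed against 3 technical explanations. GC content was argued against, since their medians exceeded those of lists matched on signal and GC content by 0.28 and 0.24. Dim spots were argued against by the members brighter than the median gene, whose medians were 0.19 for 25 p53 targets and 0.18 for 40 replication genes. Unequal RNA degradation was examined with probes at least 1000 bp apart in the same gene. Their 3' minus 5' difference had a median of 0.039 (0.028 to 0.047, 3883 genes). The interval was wholly positive, so a small difference between the arrays was present. The value is well under both list medians and argues against a large difference in degradation across all genes. It was not measured for the p53 target and replication genes alone. An effect of entecavir and other differences between the cultures both stay open, and neither was tested, as that needs replicate cultures.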
